A study of Caenorhabditis elegans with 4 samples.

How the data were processed

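Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map where the CES-1 protein sat on the genome in embryos of the nematode Caenorhabditis elegans. CES-1 is a zinc-finger transcription factor of the Snail family with a known role in programmed cell death. Per the labels, the embryos came from strain OP174, which carries a transgene encoding CES-1 fused to GFP, and the population held males and hermaphrodites. Per the labels' protocols, worms were grown at 20 degrees Celsius, crosslinked with 2% formaldehyde and quenched with 100 mM Tris. Sonicated chromatin was then precipitated with anti-GFP antibodies, and part of each extract was kept as input DNA. The labels list 4 libraries, 2 ChIP and 2 Input. Nothing in the labels says whether the ChIP replicates came from separate cultures, so the spread between them may be technical.

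The peak lists used were one for each ChIP replicate and a combined one for the series. Per the file headers, the genome build was WormBase WS220, and the source field of the lists names SPP (a ChIP-seq peak caller) and IDR (the irreproducible discovery rate, which compares ranks between replicates). Versions, thresholds, the aligner and the way the combined list was made are not given in the sources used here. Each peak carries the authors' score, whose scale is not stated in the deposited lists. The score reaches a ceiling shared by many peaks in each list. Apart from an alternative setting that took Pearson's r on log10 scores, it was used only to rank peaks within a list. Peaks also carry a number from the authors, which follows the order of the score, and ties at the ceiling were broken by this number. The highest number at the ceiling was 4629 in the combined list, which equals the count of peaks there. The lists hold no read counts, so sequencing depth is unknown. No list of the Input libraries was analysed here, and input DNA enters only through the authors' calls.

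Regions were compared with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9. Coordinates are those of WS220, counted from 1. Regions of the replicates were called shared when they overlapped by at least 1 bp. The overlap expected by chance came from 1000 random circular shifts of one list along each chromosome, with a one-sided permutation p, and from 200 shifts under the alternative settings. Agreement of ranks was measured with Spearman's rho over overlapping pairs, with a bootstrap interval. It is a relation across regions, which are not independent replicates. Shares of regions have 95% Wilson intervals that cover counting error only. Each chromosome's share of the combined regions was compared with its share of the genome by a two-sided exact binomial test, with Benjamini-Hochberg adjustment over 6 chromosomes. For chromosome shares in each replicate on its own, the 8678 best-ranked nuclear regions were used, as many as the combined list holds.

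The tests of overlap, rank agreement, recovery and chromosome shares were fixed before the data were examined. Lengths of the WS220 chromosomes were not used here, and the plan then called for counts alone. The span of each chromosome up to the last region of any list was used as the denominator instead, a choice made after the lists had been seen. The densities in 1 Mb windows, the central part of each chromosome (the middle 33.3% of its span), the distances between regions, the strong regions left out of the combined list and the regions on mitochondrial DNA were also examined only after the lists had been seen. Densities in windows were compared by a two-sided permutation test with 100000 resamples, and ratios of densities have intervals from 5000 bootstrap draws of windows. These treatments, and the binomial test, take neighbouring regions or windows as independent, which they are not. Rotation of all regions along the joined chromosomes (20000 rotations) keeps their spacing and gave a second p for each chromosome, with Benjamini-Hochberg adjustment over 6. A one-sided rotation test of X with 1000 rotations was run first (permutation p = 0.0340). With the same rotations the two-sided permutation p was 0.0919 for X and 0.04995 for V. The number of rotations was then raised, which gave a one-sided permutation p of 0.0325 for X, and the other chromosomes and the adjustment were added last. Circular shifts did the same for the central parts, with 1000 shifts for each chromosome and 20000 for the autosomes together. Random placement of regions within 1 Mb windows (200 draws) gave the share expected to lie within 1 kb of another.

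The steps were tested on simulated data. In a list of 10000 regions, 49.5% were copied into a second list, and 49.1% were recovered after the chance overlap was taken off. Lists of 8678 regions with an X density 1.4 times that of the autosomes gave a mean ratio of 1.39, and the window test called all 20 of them. It called 6 of 100 lists with even density. The simulated regions were placed independently of each other, so these counts do not show how often the window test errs on clustered regions.

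The gene annotation at hand belongs to the WBcel235 assembly, another build than WS220, so it was not joined to the regions and no coordinates were converted. Positions relative to genes, enrichment of 17 gene lists and enrichment of the 10 classes of E-box hexamer had been planned and were not run. The rule for named genes had been to name egl-1, ces-1 and cdc-25.2, the genes at the 12 best-ranked combined regions and up to 4 members of each gene list. It was not applied, and regions are named by their position alone. For the same 12 regions, the position is given in place of the gene.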

Results

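CES-1 was profiled in embryos through a GFP fusion, with 2 ChIP replicates and 2 Input libraries. The question was where in the genome CES-1 binds at this stage. The combined list held 8678 regions, of which 8080 remained after overlapping regions were merged, and these covered 3.21 Mb. Each replicate list held 30000 regions, which covered 11.9 Mb in replicate 1 and 11.7 Mb in replicate 2 after merging. The same number in both lists may be a set limit, so it cannot be read as a count of binding regions. Shares taken over all 30000 regions depend on where the lists end. Widths in the combined list ran from 110 to 1307 bp, and 5982 regions (68.9%) were 440 bp wide. The authors' score was at its ceiling of 3.97 in 4629 combined regions (53.3%). It stood at its ceiling in 4148 regions of replicate 1 and in 5628 of replicate 2. The score cannot order regions at the ceiling, and the authors' peak numbers were used there.

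The best-ranked combined region lay on chromosome I at 6799392 to 6799921, and it overlapped peak number 1 of both replicates. The region ranked second, on X at 16991313 to 16991788, overlapped peak number 2 of both. The next on X were at 10765961 to 10766513, numbers 3 and 6 in replicates 1 and 2, and at 5129361 to 5129857, numbers 6 and 3. On chromosome I, the region at 4171925 to 4172654 held numbers 12 and 5, and that at 10032856 to 10033379 held numbers 9 and 21. Chromosome V had 3 of the 12 best-ranked regions. These lay at 10721259 to 10721720 (numbers 8 and 9), at 9765343 to 9766176 (numbers 11 and 8) and at 4357322 to 4357841 (numbers 13 and 19). On chromosome II, the region at 8589182 to 8589650 was number 10 in both replicates, and that at 5844552 to 5845173 was number 7 and number 15. The region on chromosome IV at 13240497 to 13240938 was number 4 in replicate 1 and number 25 in replicate 2. Chromosome III entered at rank 16, with the region at 13060945 to 13061414 (numbers 16 and 24). The genes at these positions were not analysed here. All of the 100 best-ranked combined regions overlapped peaks at the score ceiling in both replicates, and 77 of them overlapped a peak among the first 100 of each.

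The replicates were compared to see which regions were found in both. In replicate 1, 20150 of the 30000 regions (67.2%, 95% Wilson interval 66.6 to 67.7) overlapped a region of replicate 2. In the other direction, 67.6% of the replicate 2 regions overlapped replicate 1. Circular shifts gave 22.4% and 22.6%, so the observed shares were 3.00 times the chance level in both directions (one-sided permutation p = 0.000999, the smallest that 1000 shifts can give). With 50% reciprocal overlap the share of replicate 1 regions found in replicate 2 was 53.9%, 4.64 times the chance level, and with centres within 200 bp it was 55.01%, 4.75 times. Of the first 1000 peaks of replicate 1, 99.7% overlapped some region of replicate 2, and the converse share was 99.0%. Among the 8678 best-ranked of each list, 80.3% of the replicate 1 regions overlapped replicate 2, against 6.97% after shifts. The scores of 17308 overlapping pairs were related with a Spearman's rho of 0.724 (95% bootstrap interval 0.716 to 0.733). This is a relation across regions, which are not independent replicates.

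**Figure D1:**
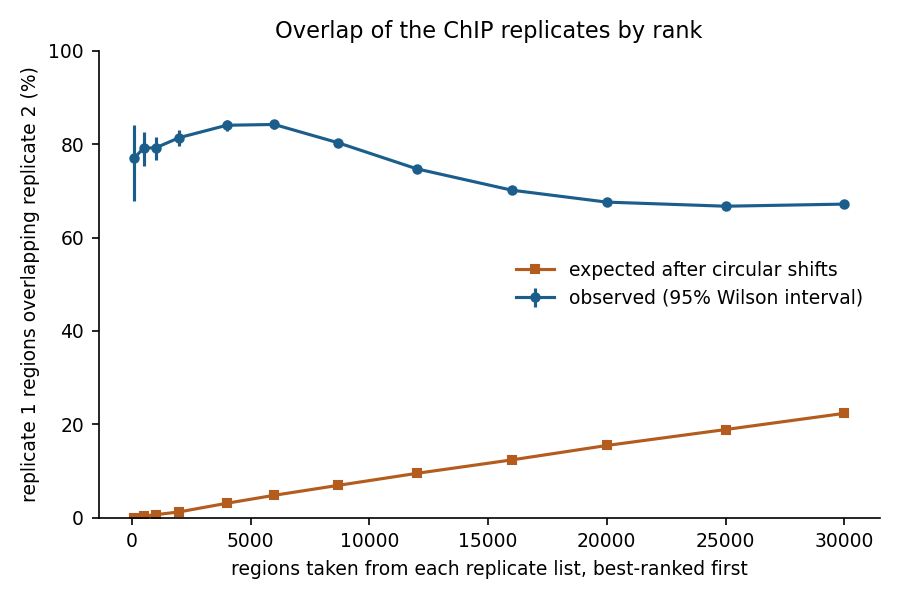
Share of replicate 1 regions that overlapped a replicate 2 region (y axis, %) when the same number of best-ranked regions was taken from each list (x axis, regions). Blue circles are the observed shares with 95% Wilson intervals and orange squares are the mean of 50 circular shifts; the observed share was 80.3% at 8678 regions and 67.2% at 30000.

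The combined list was set against the replicates to see how many of its regions each one held. In both replicates together, 8565 of the 8678 combined regions (98.7%, 95% Wilson interval 98.4 to 98.9) were found. Replicate 1 alone held 41 of the others and replicate 2 alone held 72, and 0 lay in neither. The combined list is the series' own list of these same replicates, so its high recovery in them is no independent check. In replicate 1, 34.3% of all regions overlapped the combined list, and in replicate 2 it was 34.6%. The share was 97.9% and 97.1% for peak numbers 1 to 5000. It was 5.84% and 5.08% for numbers 25001 to 30000.

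Binding regions were counted per chromosome. Chromosome X held 2009 combined regions, 23.2% of all regions on 17.7% of the genome span, or 113 per Mb. Chromosome V held the fewest for its span, with 1209 regions, 13.9% on 20.9% of the span, or 57.8 per Mb. Chromosome I held 1549 regions (103 per Mb), chromosome III 1330 (96.5 per Mb) and chromosome IV 1287 (73.6 per Mb). By the two-sided exact binomial test, X was above its share of the span (adjusted p = 1.51e-37) and V below it (adjusted p = 1.21e-61). Chromosomes I and III were also above theirs and IV below, with exact binomial adjusted p of 1.06e-12, 3.06e-05 and 8.55e-11. Chromosome II, with 1294 regions and 84.7 per Mb, did not differ from its share (exact binomial adjusted p = 0.403). In the replicates' own best-ranked regions, X held 22.9% ± 0.269 (SD, n = 2), V 13.9% ± 0.326 (SD, n = 2) and I 17.7% ± 0.456 (SD, n = 2). Regions are clustered along the chromosomes, so these binomial p-values are too small. When the whole genome was rotated, which keeps the clustering, none of the 6 chromosomes passed the two-sided permutation test after adjustment. The permutation p was 0.0413 for V (0.248 after adjustment over 6 chromosomes) and 0.0956 for X (adjusted 0.287). Each chromosome is a large part of the span, so rotations give few independent placements and the test may have little power. Not passing it does not show that the shares were even.

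**Figure D2:**
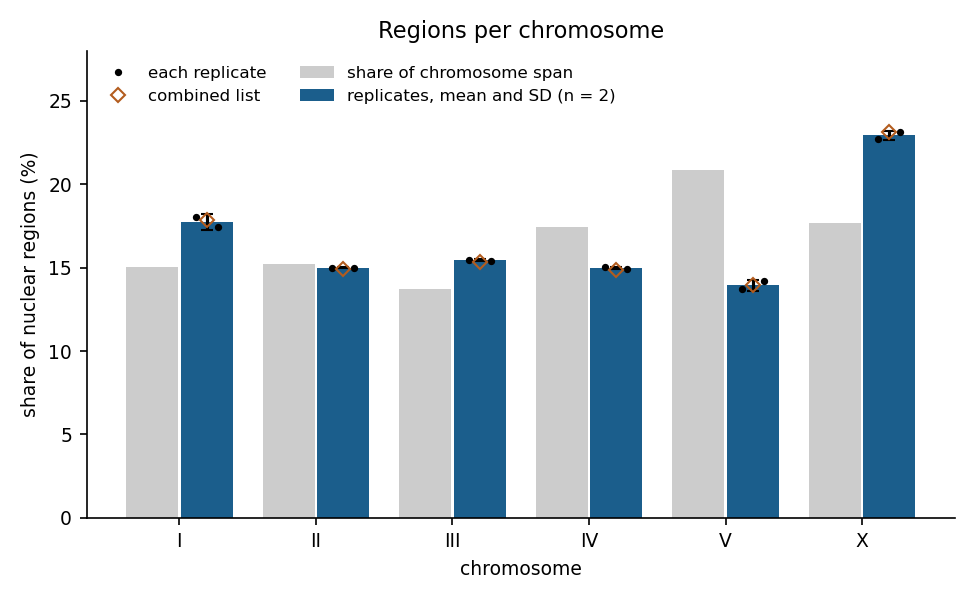
Share of nuclear regions on each chromosome (y axis, %) beside the chromosome's share of the genome span in grey. Blue bars are the mean of both ChIP replicates, error bars the SD (n = 2), black points the replicates and open diamonds the combined list; X reached 23.2% in the combined list on 17.7% of the span.

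The position of regions along the chromosomes was examined in 1 Mb windows. The 17 windows of X held 115 ± 21.9 regions (SD over windows) and the 80 autosomal windows 80.4 ± 33.1. The ratio was 1.44 (95% bootstrap interval 1.28 to 1.61; permutation p = 5e-05 over windows, which are not independent). The rotation test stated above treats the same excess with the spacing kept and did not pass. Autosomal regions were denser near the middle of chromosomes. The central part of the 5 autosomes, defined as the middle 33.3% of each span, held 2803 of 6669 regions (42.03%), the share being 33.3% if regions were spread evenly (two-sided permutation p = 0.00195 with 20000 circular shifts). The central share was 48.6% on V, 45.4% on II, 40.3% on I, 39.7% on IV and 37.0% on III. No autosome passed the circular-shift test alone (permutation, adjusted p from 0.518 to 0.597). On X the central share was 35.4%. The ratio of central to outer density was 1.46 on the autosomes (95% bootstrap interval 1.25 to 1.71) and 1.03 on X (0.886 to 1.21). The autosomal ratio was 1.41 times that of X (95% bootstrap interval 1.14 to 1.75).

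**Figure D3:**
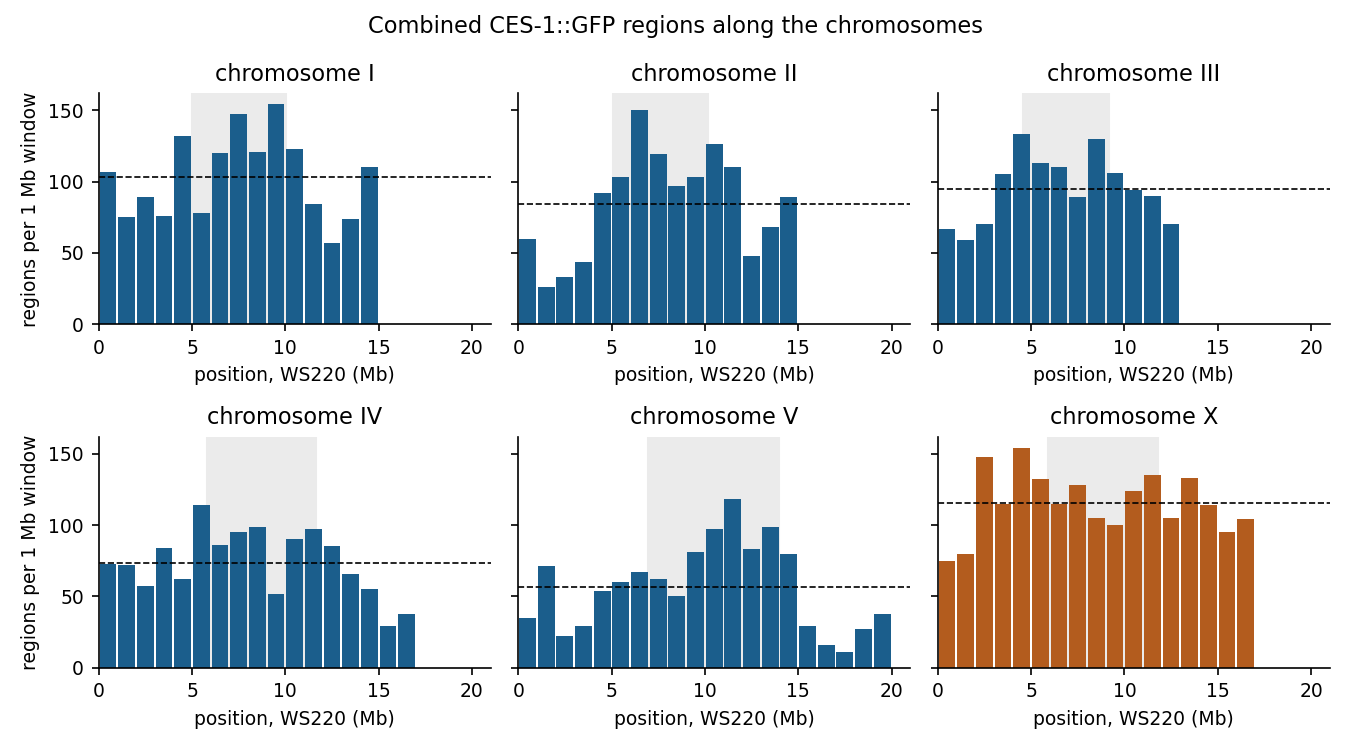
Combined CES-1::GFP regions in each 1 Mb window (y axis, regions per window) along the 6 nuclear chromosomes (x axis, WS220 position in Mb). Shading marks the central part (33.3% of the span) and dashed lines the mean of the chromosome's windows; X averaged 115 regions per window and the autosomes 80.4.

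Several stretches held many regions. The densest 100 kb window lay on chromosome II at 6800001 to 6900000, with 38 regions (34 after merging), and 40 and 39 among the best-ranked regions of replicates 1 and 2. Next were X at 7200001 to 7300000 with 32 regions, and 3 windows with 31 regions each. These were I at 7300001 to 7400000, II at 6100001 to 6200000 and X at 5800001 to 5900000. The median window held 8 regions. Of 999 windows, 52 held none, and 26 of these were among the 209 windows of V against 2 of 177 on X. The longest stretch without a combined region, 461 kb, was on V at 17076862 to 17538227, where the replicate lists held 7 and 6 regions. On IV, the stretch of 329 kb at 16049170 to 16377781 held 56 and 51 replicate regions. Of all combined regions, 30.2% lay within 1 kb of another, against 17.8% under random placement (one-sided permutation p = 0.00498, the smallest that 200 draws can give). After overlapping regions were merged the shares were 18.6% and 16.6%, with the same permutation p. The observed share fell from 1.69 to 1.12 times the random one, so most of the excess came from regions that overlapped each other. The combined list held 66 regions that repeated the interval of another.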

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

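All tests in this part were chosen after the results had been seen, and no biological explanation was tested, since the design holds no second condition. Intervals of ratios come from resampled windows, which are not independent of their neighbours.

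Regions on mitochondrial DNA were part of the replicate lists when these were set against each other and against the combined list, but not of the counts per chromosome. They were singled out because replicate 1 listed 23 such regions and replicate 2 listed 25, while the combined list held 0. Their best peak numbers were 77 and 214, and 22 and 25 of them overlapped the other replicate. These regions covered 7897 bp in replicate 1 and 8385 bp in replicate 2, of a span of 13863 bp. Much overlap is therefore likely by chance, and no chance level was computed for it, so these counts do not show a repeatable signal.

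The density of regions on X was 1.44 times that of the autosomes, and chance clustering stays open for this excess, which did not pass the two-sided rotation test. Regions of both replicates outside the combined list, which can be weak binding or background, had an excess too, with a ratio of 1.22 (95% interval 1.12 to 1.35). The combined ratio was 1.18 times theirs (1.06 to 1.31). Background among the regions outside could lower their ratio, so this cannot decide whether the gain was equal at every strength. The 4339 best-ranked combined regions had 1.33, so the excess did not rise steadily with rank. Leaving out the densest 10% of windows gave a ratio of 1.49 (1.32 to 1.71), which argues against a few dense windows. Within the central parts the ratio was 1.16 (1.02 to 1.32), so sparse outer parts of the autosomes may account for much of the excess. Whether they account for the whole is undecided, since the central part of X had only 6 windows, which are not independent.

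Autosomal regions were denser in the central parts, with a ratio of 1.46. Replicate regions outside the combined list went the opposite way, with a ratio of 0.772 (0.684 to 0.878). The combined ratio was 1.89 times theirs (1.64 to 2.17), so no surplus in the centres was seen among the regions outside. Regions that overlapped the combined list had been taken out of that set, which lowers its density where combined regions are dense. It may also hold background, so this cannot decide whether weak binding was denser in the centres. Merging overlapping regions gave 1.45 (1.25 to 1.69), which argues against repeated listing. Each replicate's own best-ranked regions, taken without the combined list, gave 1.42 (1.22 to 1.66) and 1.53 (1.32 to 1.79), which argues against the making of the combined list as the cause. The calling and scoring of regions, shared by both replicates, was not tested.

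Among 3513 nuclear pairs at the score ceiling in both replicates, 32 (0.911%) overlapped no combined region. The best-ranked lay on I at 9625976 to 9626187, number 751 in replicate 1 and 1194 in replicate 2. Their median rank difference was 0.26 on the log2 scale (95% interval 0.19 to 0.43), against 0.39 in matched included pairs (permutation p = 0.0867), so disagreement in rank cannot be told apart from other causes, with few pairs that were all taken at the ceiling in both replicates. The share of them beyond the 95th percentile of matched pairs, 9.38%, was computed next. It pointed the other way from the medians, being above the share that this percentile leaves among matched pairs. It rests on only 3 of the 32 left-out pairs, so it decides nothing. The nearest combined region lay at a median of 9.655 kb, which argues against one placed slightly aside. A filter on listed regions stays a possible explanation and was not tested.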

How the results depend on the processing

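Results were recomputed under 39 alternatives for 9 results, of which 31 kept their direction and their side of the threshold or moved by less than their interval, and 0 reversed. The alternatives for X density, central density, rotation of the genome, distances within 1 kb, merged regions, peak numbers, and recovery by centres within 200 bp were chosen after seeing the data. When the whole genome was rotated, the X share of 23.2% and the X to autosome ratio of 1.44 no longer passed the threshold (permutation, adjusted p = 0.287), nor did the V share of 13.9% (permutation, adjusted p = 0.248). By construction, rotation keeps the clustering of regions. Rank agreement was 0.615 over pairs that overlap a combined region and 0.745 with peak numbers in place of scores. Recovery of combined regions in both replicates was 83.7% with 50% reciprocal overlap, 97.3% with centres within 200 bp and 99.4% for the 4339 best-ranked regions. For these 5 values the cause was not tested. For the settings without 1 replicate, the best-ranked regions of the other were used, and the combined list was not made anew. The X share was 22.7% in replicate 1 and 23.1% in replicate 2, and the V share 13.7% and 14.2%. These are the values behind the means and SDs given in Results, so they are no added check. The other settings foreseen for positions relative to genes (promoter windows, best-ranked regions, single replicates), gene lists (the same, nearest start sites, shifts) and E-boxes (windows, controls, best-ranked regions, single replicates) were not run, because the annotation at hand was of another build. No paired analysis was possible because no list of the Input libraries was used here. Depth is unknown, so nothing can be said of regions that deeper sequencing would add.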

Other observations

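The comparisons in this part were all chosen after the data had been seen, and they are given as values.

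The density of chromosome V was 0.638 of that of the other autosomes in the combined list (95% bootstrap interval 0.489 to 0.797) and 0.637 among replicate regions outside the combined list (0.548 to 0.736). The quotient of these was 1.002 (0.761 to 1.28). The share of combined regions over the share of the span was 1.19 on I, 1.11 on III and 0.85 on IV. Outside the combined list, replicates 1 and 2 gave 1.15 and 1.14 on I, and 1.19 and 1.15 on III. The excess on I and III was therefore not particular to the combined regions. On IV the values outside were 1.07 and 1.02. On X, the share of regions was 21.6% among peak numbers 1 to 1000 and 23.4% among the rest, a difference that did not pass Fisher's exact test (two-sided p = 0.232). This split does not show that the X share is unrelated to rank. In the 4339 best-ranked combined regions it was 21.7%, against 23.2% in the whole list. The whole list contains those regions, so the share among the remaining, lower-ranked ones was above 23.2%. By this split the X share was lower among better-ranked regions, a difference that was not tested.

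Few strong regions of 1 replicate were absent from the full list of the other. Overlap with a weak region also counted as presence. Regions strong in 1 replicate and weaker in the other are therefore not among those counted here. Of 4134 nuclear regions at the score ceiling in replicate 1, 36 (0.871%) overlapped none of the 30000 regions of replicate 2. In the other direction it was 149 of 5613 (2.65%). The best-ranked of these lay on II at 8162205 to 8162509 and was number 144 in replicate 2. Of the 36 and 149 regions, 17 and 41 were in the combined list. Of the 32 nuclear pairs left out of the combined list, 1 was on X, against 734 of the 3481 pairs included (21.1%; Fisher's exact test, two-sided p = 0.00795). Chromosome IV held 9 of them and chromosome V held 7.

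Among the 2544 combined regions up to peak number 4000 with a width other than 440 bp, peak number and width were related with a Spearman's rho of -0.768, so the better-ranked of them were wider. This does not hold for the whole list. The median width was 379.5 bp for peak numbers 1 to 500 and 234 bp for numbers 1001 to 1500, and it was 440 bp in each set of 500 numbers from 2501 to 8500, the commonest width of the list. The least width, 110 bp, was that commonest width divided by 4. Widths of 440 bp made up 0.8% of numbers 1 to 500 and 99.2% of the last such set.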
